A study of Homo sapiens with 6 samples.

How the data were processed

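The samples were MDA-MB-231 cells, an established line from a breast cancer without hormone receptors or HER2 amplification, exposed to riluzole at 25 µM or to the solvent DMSO (vehicle). There were 3 samples per group, and each was measured on 1 single-colour Illumina bead array. Per the labels' protocols, RNA was purified with a QIAGEN RNeasy Plus kit, and biotin-labelled cRNA was made with an Illumina TotalPrep-96 kit. The treatment time is 24 hours in the labels of the samples, whereas the title and design of the series speak of overnight treatment. The array type and the scanner software are not given in the sources used here. The labels give the samples the numbers 1 to 3 within each group and do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical.

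The authors deposited a table of signal intensity per probe, which per the file headers is the average bead signal of each probe on each array. Its values are linear, are all above 0, and were neither background-subtracted nor normalized between arrays. Beside each intensity the authors deposited a detection p-value, which moves in steps of 1 over the 770 negative control probes and so is the rank of the probe among those controls. The authors also deposited processed values for the same arrays, as a linear intensity whose making is not given in the sources used here. Set against the signals of the same array, these values rose with the raw intensity of dim probes at a slope between 0.818 and 0.914 per array. Bright probes were left out of that fit, so a single factor per array is not established. The processed values are not log values and not centred per gene, their direction is that of the signal, and between 19.4% and 22.3% of them per array lie below 0. Their column medians lie between 20.6 and 21.6, and what set the slopes stays unknown. They served as an alternative only, with values under 16 set to 16 before log2.

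Of 47231 probes outside the 979 control rows, 43907 carried 1 gene symbol, 0 carried several and 3324 were left unnamed, 54 of them because a date stood in place of the symbol. Symbols were brought up to date through the names and synonyms of the RefSeq gene table of GRCh38.p14, used for names alone. By probe, 27036 symbols were current, 4626 were renamed through a synonym and 12245 were not placed by that table and kept the array's name. A synonym shared by several genes also kept the array's name.

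Intensities were processed with limma 3.58.1 in R 4.3.3. The neqc function subtracted background by normexp, with parameters taken from the detection p-values, added an offset of 16, applied quantile normalization between arrays and took log2. The control rows were left out beforehand. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were kept, which left 20788 probes, 19675 of them with a gene name. Each gene was represented by its brightest kept probe over all 6 arrays, giving 14887 genes from 30818 on the array. A linear model with group as its only term was fitted with lmFit and eBayes, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are riluzole over vehicle on this background-corrected scale, on which the offset of 16 draws the folds of dim probes toward 1. Intervals are 95% intervals of the same fit. A gene not detected on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the higher, per array, of the lowest detected signal and the gene's own signal.

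Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists tested. A list needed at least 5 detected members. Of 34 lists 32 were tested, and 2 had fewer. Members past the threshold were counted over all genes and also adjusted over the list alone. The grouping, the tests, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose groups did not overlap, up to 4 members of each list past the threshold with the smallest p, and, whatever their values, a fixed set of genes that includes SLC7A11, SLC3A2, SLC1A1, SLC1A3, CYP1A1, CYP1B1, TIPARP, ATF4, DDIT3, CDKN1A, CCND1 and MKI67. Some genes that the rule names are not reported here. Other genes named in the text were chosen after their values were seen, and the text says so.

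The alternatives were quantile normalization without background correction, median scaling in place of quantile normalization, the authors' processed values, no detection filter, detection p under 0.01 on all 6 arrays, eBayes with an intensity trend and robust settings, array weights, the replicate number as a block, the mean of a gene's kept probes, an added fold threshold of 1.5, and each array left out in turn. Lists were also tested with camera's estimated correlation and with fry. One alternative, neqc with the negative control probes in place of the detection p-values, was chosen after seeing the data. No scan date or slide was used here, so no batch could be tested.

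The fit was tested on simulated data made from these arrays, 17648 genes in that step, with noise added on top of the measured noise. Of simulated changes of 0.5, 1 and 2 on the log2 scale, 0% of 66, 29.7% of 64 and 61.3% of 62 passed the threshold, and 5 of 62 calls fell on unchanged genes. A list of 30 genes shifted by 0.4 had a camera adjusted p of 8.37e-23, and an unchanged list 0.943. The simulated noise was independent between genes, so it cannot show how camera behaves where the genes of a list vary together. The number of arrays limits the precision, and many changes of 2-fold were missed in this simulation. Its noise was above the measured noise, and the share missed at the measured noise was not tested. Plots were drawn with matplotlib 3.10.9.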

Results

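Genome-wide transcript levels were measured in MDA-MB-231 cells, a human triple-negative breast cancer line, after treatment with riluzole at 25 µM or with DMSO as vehicle. Riluzole is a drug used in amyotrophic lateral sclerosis that lowers glutamate release and blocks sodium channels. The series asks which genes are differentially expressed between the 2 treatments, with 3 arrays per group. The sample labels give 24 hours of treatment, and the series title calls it overnight. Between 20516 and 20959 of 47231 probes were detected per array. The median raw signal lay between 127 and 133 per array, and the negative control probes averaged between 107 and 111. Pearson correlations between arrays, taken across genes, which are not independent replicates, were 0.992 to 0.994 within groups and 0.989 to 0.991 between groups. The first principal component held 35.7% of the variance and separated the groups, and the median replicate SD of a gene was 0.147 log2 units with vehicle and 0.139 with riluzole.

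With riluzole, transcripts of cholesterol synthesis (camera adjusted p = 1.59e-12) and of DNA replication (1.59e-08) fell as groups, and transcripts of mitosis rose as a group (3.73e-20). These values rest on the preset inter-gene correlation of 0.01. With camera's estimated correlation the adjusted p was 0.0190 for cholesterol synthesis, 0.0369 for DNA replication and 0.0124 for mitosis. INSIG1, which retains the SREBP processing complex in the endoplasmic reticulum, was 2.17-fold lower (95% CI 1.79 to 2.64, n = 3 per group). The mitotic cyclin CCNB1 was 1.82-fold higher (1.53 to 2.17), and CCNE2, a cyclin of S-phase entry, was 1.78-fold lower (1.5 to 2.12). ATF4, a transcription factor of the amino acid and stress response, was 1.76-fold higher (1.48 to 2.10), and ASNS, the asparagine synthetase it regulates, was 1.84-fold higher (1.52 to 2.22). FASN, the fatty acid synthase, was 1.69-fold lower (1.44 to 1.99). These single-gene calls depended on the arrays used. Of the 6 fits with an array left out, 4 kept the call of INSIG1 and 2 that of CCNB1. The calls of CCNE2, ATF4 and ASNS each held in 1 of these fits, and that of FASN in 0.

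In the limma fit 176 of 14887 genes passed the adjusted threshold, 112 higher and 64 lower with riluzole. Of these, 36 differed by 2-fold or more, and 162 passed a fold of 1.5 as well, 101 higher and 61 lower. The median absolute log2 fold change of the 176 genes was 0.77. In each of them the 3 riluzole arrays lay on one side of the 3 vehicle arrays. Over all tested genes 22.7% had groups that did not overlap, where chance gives 10%. The count moved with the arrays used, the filter and the variance model. It was 41, 21 and 24 without vehicle replicate 1, 2 or 3, 41, 30 and 21 without riluzole replicate 1, 2 or 3, 94 with the authors' processed values, 563 without background correction, 70 without a detection filter, 360 with detection under 0.01 on all 6 arrays and 661 with an intensity trend and robust variance. All of the 52 named genes past the threshold kept their direction in every setting and every fit with an array left out that tested them. Groups that do not overlap tend to keep their direction when an array is removed, so the latter is little support. With each array left out, 13 of the 52 stayed past the threshold. Among them were LOC100170939, SNORD46, P8, LOC643995, LOC728844, LOC153561, ADM2, TROAP, MKX, TERC, SNORA16A and NUPR1.

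The genes with the largest rise were mixed in kind. TROAP, a spindle protein of mitosis, went from 10.03 ± 0.14 to 11.45 ± 0.09 log2 units (mean ± SD, n = 3), 2.68-fold higher with an adjusted p of 0.00586. MKX, a homeobox transcription factor, was 2.52-fold higher (adjusted p = 0.00586), and ADM2, a peptide of the adrenomedullin family, was 2.74-fold higher (adjusted p = 0.00934). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 4.0-fold higher on its brightest probe (95% CI 2.68 to 5.95, adjusted p = 0.0168). Its other detected probe gave a log2 fold change of 0.19 (adjusted p = 0.510 over probes), so the size of the ANGPTL4 change differs between probes. The ANGPTL4 call was lost without vehicle replicate 2 (adjusted p = 0.0660), without riluzole replicate 1 (0.0504) or 3 (0.0679), and without riluzole replicate 2 (0.481), where the other probe stood for the gene. Its adjusted p ran from 5.29e-05 to 0.418 over the other settings, the highest with detection under 0.01 on all 6 arrays. The small nucleolar RNA SNORD46 was 3.85-fold higher (adjusted p = 0.00101). SNORA17B, named SNORA43 on the array, was not detected in any vehicle array and was at least 2.63-fold higher (adjusted p = 0.0190). The other genes with the largest rise keep their array names, which the gene table did not place or, for P8, gives as a synonym of several genes: LOC100170939, P8, LOC643995 (3.16-fold), FLJ10213 (3.03-fold), LOC728844 (2.88-fold) and LOC153561 (2.85-fold). Of these, LOC100170939 was detected on 2 vehicle arrays and P8 on 1, so no exact fold is given for them. A further LOC153561 probe gave a log2 fold change of 0.10, and the mean of its detected probes gave 0.81. Some of these sizes were smaller with quantile normalization and no background correction, where the log2 fold change was 1.07 for SNORD46 (1.95 in the main analysis), 0.91 for SNORA17B (1.82), 0.84 for LOC728844 (1.53) and 0.84 for ADM2 (1.46), so the bound given for SNORA17B holds for the main analysis only.

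The genes with the largest fall held several noncoding RNAs. TERC, the RNA component of telomerase, went from 8.25 ± 0.20 to 6.59 ± 0.20 log2 units, 3.16-fold lower (95% CI 2.5 to 3.99, adjusted p = 0.00643). SNORA16A was 2.23-fold lower (adjusted p = 0.00643), SNORA12 2.25-fold lower (0.0304) and SCARNA18 1.97-fold lower (0.0202). LINC00472, a long noncoding RNA, was 1.99-fold lower (0.0151). RIMS2, a protein of the presynaptic active zone, was lower (0.0324) and was detected on 3 vehicle arrays and 1 riluzole array, so no exact fold is given. IL16, a cytokine, was detected on all 3 vehicle arrays and on 0 riluzole arrays and was at least 1.58-fold lower (adjusted p = 0.050, under the threshold before rounding). CDS1, an enzyme of phospholipid synthesis, was at least 1.73-fold lower (0.0458) in the same way. LOC85390 was at least 1.93-fold lower (0.0110), and LOC645313 was 2.07-fold lower (0.0243). Without background correction the log2 fold change was -1.07 for TERC (-1.66 in the main analysis), -0.51 for LOC85390 (-1.12), -0.49 for IL16 (-1.03) and -0.45 for CDS1 (-0.98), so the bounds given for the last 3 hold for the main analysis only. Small noncoding RNAs (nucleolar, Cajal body and small nuclear RNAs, with TERC and the vault and Y RNAs) were over-represented among the calls: 18 of 135 tested passed, 6 higher and 12 lower, which is 13.3% against 1.07% of the other genes (Fisher's exact test, two-sided, p = 2.70e-14, a comparison made after these genes were seen). The Fisher test takes genes as independent, whereas some of these small RNAs share a host gene and all were read on the same arrays. Its p-value therefore does not measure the spread between samples. The 117 small RNA genes not past the threshold had a median log2 fold change of -0.17. Whether the probes of these genes read the mature small RNAs was not tested.

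**Figure D1:**
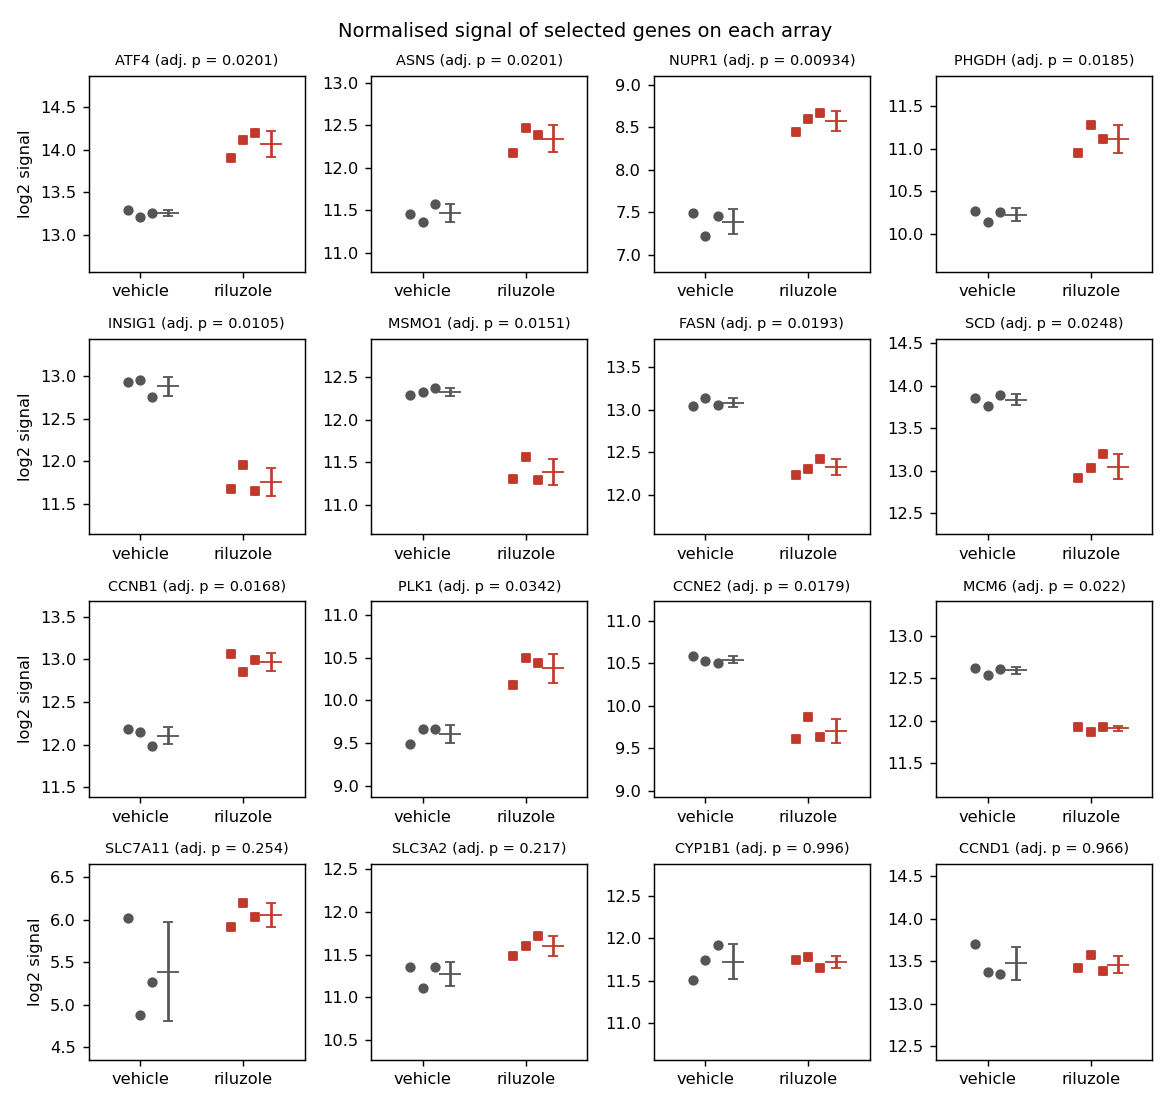
Normalized log2 signal of 16 genes (y axis) by group (x axis), with 1 point per array, 3 arrays per group, and bars at the mean ± SD. Each panel spans the same range of log2 units, so that heights can be compared between panels. ATF4, ASNS, NUPR1, PHGDH, CCNB1 and PLK1 lie higher with riluzole, INSIG1, MSMO1, FASN, SCD, CCNE2 and MCM6 lie lower, SLC7A11, SLC3A2, CYP1B1 and CCND1 did not pass the threshold, and the groups overlap for SLC7A11, CYP1B1 and CCND1.

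Of the 32 gene lists tested with camera, 9 passed the adjusted threshold, 3 higher and 6 lower with riluzole. The list of mitosis and G2/M genes had the smallest adjusted p, 3.73e-20, with a median log2 fold change of 0.54. Of its 33 detected members, 13 rose over all genes and 26 rose when adjusted over the list alone, and 0 fell by either count. CCNB1 (12.11 ± 0.10 to 12.97 ± 0.11 log2 units, adjusted p = 0.0168), the kinase PLK1 (1.71-fold, 0.0342), the centromeric histone CENPA (1.82-fold, 0.0169) and the spindle protein CKAP2 (1.69-fold, 0.0168) were among them. A further probe of CENPA gave a log2 fold change of 0.577 (limma adjusted p = 0.101 over probes). For CKAP2 a further probe gave 0.575 (0.0571), so neither passed. The proliferation marker MKI67 was 1.51-fold higher (0.0418). The list of G1/S and DNA replication genes fell (camera adjusted p = 1.59e-08, median -0.20). Of its 40 detected members, 3 fell over all genes and 14 fell when adjusted over the list alone. The 3 were CCNE2 (adjusted p = 0.0179), the replicative helicase subunit MCM6 (1.6-fold lower, 0.0220) and the uracil-DNA glycosylase UNG (1.61-fold lower, 0.0417), of which 2 further probes had the same sign and 1 the opposite. CCND1, the D-type cyclin of G1, had a log2 fold change of -0.02 (adjusted p = 0.966), and the cyclin-dependent kinase inhibitor CDKN1A one of 0.21 (0.40). Both lists kept their calls with an estimated correlation (adjusted p = 0.0124 for mitosis and 0.0369 for G1/S).

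Among lipid genes, the cholesterol biosynthesis list fell with a median log2 fold change of -0.37 (camera adjusted p = 1.59e-12; adjusted p = 0.0190 with an estimated correlation). Of its 25 detected members, 4 fell over all genes, and 15 fell and 1 rose when adjusted over the list alone. The 1 that rose was HSD17B7 (log2 fold change 0.48), a 3-ketosteroid reductase of the pathway, named here after its value was seen. Among the 4 were INSIG1 (12.88 ± 0.11 to 11.76 ± 0.17 log2 units, adjusted p = 0.0105, with a further probe at -1.06), the sterol oxidase MSMO1 (1.92-fold lower, 0.0151) and mevalonate kinase MVK (1.59-fold lower, 0.0448). Of 2 further MSMO1 probes, 1 gave -1.07 and the dimmer one 0.08. The list of fatty acid and lipid synthesis fell as well (median -0.27, camera adjusted p = 6.95e-05), but its call was lost with an estimated correlation (adjusted p = 0.102 with an estimated correlation). Of its 19 detected members, 3 fell over all genes, and 9 fell and 1 rose when adjusted over the list alone. The 3 were FASN (adjusted p = 0.0193), the stearoyl-CoA desaturase SCD (1.72-fold lower, 0.0248) and the phosphatidate phosphatase LPIN1 (1.67-fold lower, 0.0269). The 1 that rose was the lipid droplet protein PLIN2 (log2 fold change 0.42), named here after its value was seen.

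Among stress responses, the ATF4 integrated stress response list rose (median log2 fold change 0.45, camera adjusted p = 2.82e-16), and its call was lost with an estimated correlation (adjusted p = 0.117 with an estimated correlation). Of its 34 detected members, 6 rose over all genes and 19 rose when adjusted over the list alone, with 0 falling. NUPR1, a stress-induced nuclear protein, was 2.27-fold higher (adjusted p = 0.00934), PHGDH, the first enzyme of serine synthesis, 1.85-fold (0.0185), GPT2, a mitochondrial alanine aminotransferase, 1.79-fold (0.0151) and ASNS 1.84-fold (0.0201). ATF4 itself went from 13.26 ± 0.04 to 14.07 ± 0.15 log2 units (adjusted p = 0.0201). Of its further probes, 1 gave a log2 fold change of 1.0 and the dimmest one -0.09. DDIT3, a transcription factor of prolonged stress, had a log2 fold change of 0.91 with non-overlapping groups and did not pass (adjusted p = 0.115, from 0.00968 to 0.214 over the other settings, 2 of which put it past the threshold). The metallothionein list, cysteine-rich metal-binding proteins, also rose (median 0.38, camera adjusted p = 3.76e-05; adjusted p = 0.0658 with an estimated correlation). Of its 8 detected members, 2 rose over all genes, MT1H (1.96-fold, 0.0278) and MT1F (1.62-fold, 0.0445), and 4 rose when adjusted over the list alone. The unfolded protein response list missed the threshold (adjusted p = 0.0540, median 0.12, 17 of 22 members positive), as did the lists of NRF2 targets (0.503), heat shock (0.139), hypoxia (0.723) and the p53 pathway (0.963). From them HSPB8, a small heat shock protein, was 1.75-fold lower (0.0490) and PLK2 1.56-fold lower (0.0420).

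A further 3 lists fell and lost their calls with an estimated correlation. The YAP/TAZ target list had a median log2 fold change of -0.28 (camera adjusted p = 0.000130; adjusted p = 0.0658 with an estimated correlation). Of its 20 detected members, 0 passed over all genes in the limma fit, and 6 fell and 1 rose when adjusted over the list alone. The largest of these falls were the kinase LATS2 (-0.92) and the matrix protein CCN2 (-0.57), and the 1 that rose was AMOTL2 (0.37), all 3 named after their values were seen. The ribosome biogenesis and MYC list had a median of -0.14 (camera adjusted p = 0.00474; adjusted p = 0.103 with an estimated correlation). Of its 25 detected members 1 fell by either count, over all genes and adjusted over the list alone, the spermidine synthase SRM (1.69-fold lower, adjusted p = 0.0312). The list of NF-kB and inflammatory cytokine genes had a median of -0.09 (camera adjusted p = 0.0268; adjusted p = 0.358 with an estimated correlation), and it also missed the threshold without vehicle replicate 3 (0.137) or riluzole replicate 1 (0.120). Of its 24 detected members 12 were higher and 12 lower by sign, 1 fell over all genes, the NF-kB inhibitor NFKBIA (1.52-fold lower, 0.0487), and 8 fell when adjusted over the list alone. In each of the 9 lists past the threshold, the estimated correlation gave the highest adjusted p of the 12 alternatives.

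**Figure D2:**
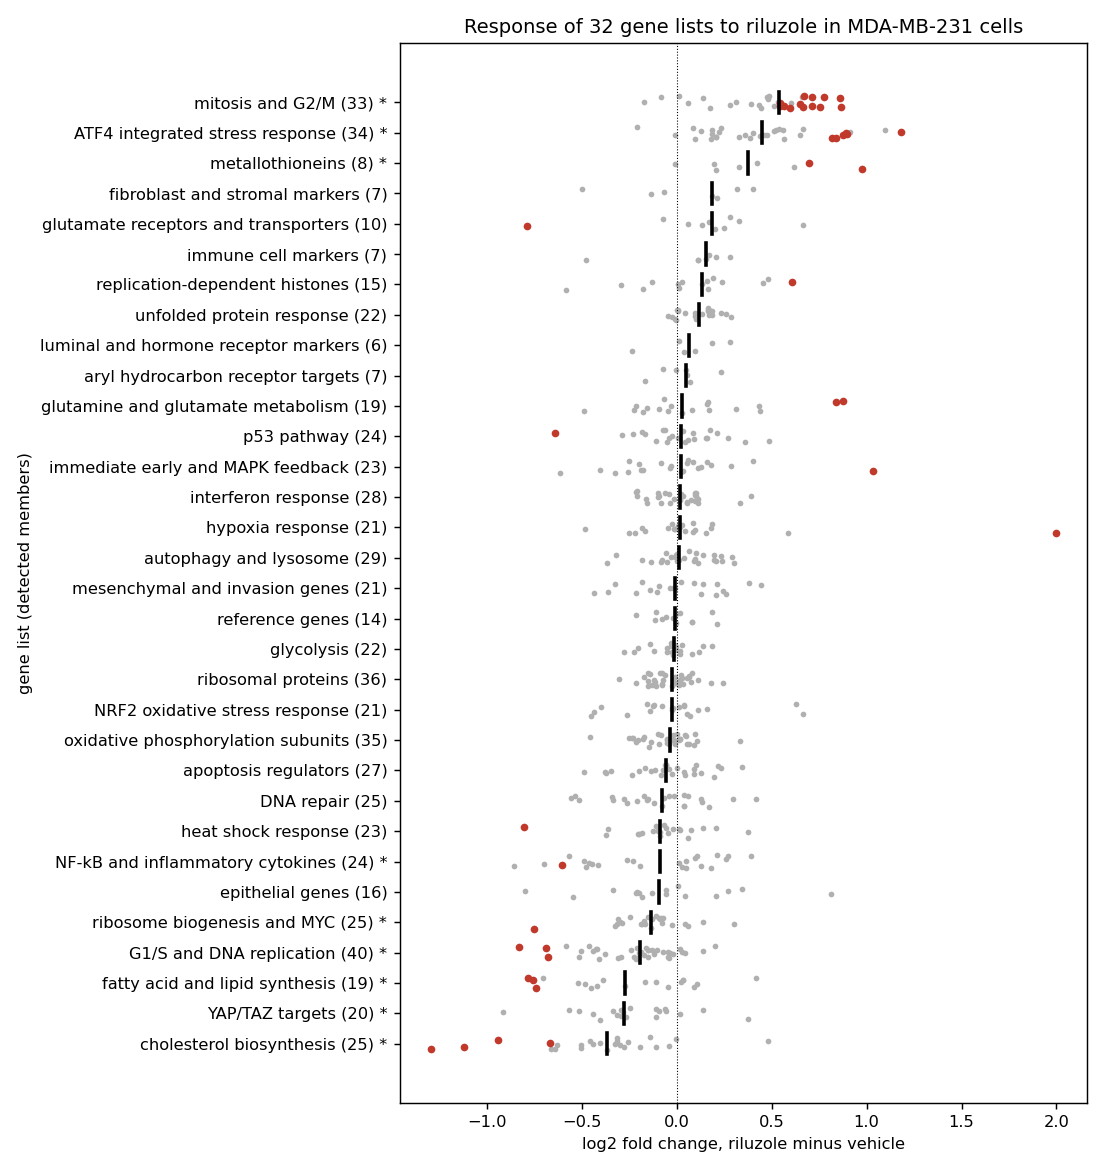
Log2 fold change, riluzole over vehicle (x axis), of each detected member of the 32 tested gene lists (y axis, ordered by median, with the number of detected members in brackets). Points are genes, red where the limma adjusted p is under 0.05 and grey otherwise, black bars are list medians, and an asterisk marks a camera adjusted p under 0.05. Mitosis and G2/M has the highest median at 0.54, followed by the ATF4 list at 0.45 and the metallothioneins at 0.38, and cholesterol biosynthesis has the lowest at -0.37.

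The glutamate transporter SLC1A1 was not detected on any of the 6 arrays, with a raw signal of 115 ± 10.5 with vehicle and 118 ± 9.73 with riluzole. Of 37 glutamate receptor and transporter genes 10 were detected, 8 of them with a positive log2 fold change, and the list did not pass (adjusted p = 0.237). It passed with detection under 0.01 on all 6 arrays (0.0212), the lowest of its 12 alternatives, which ran up to 0.792. By both counts, over all genes and adjusted over the list alone, 1 member fell, HOMER1, a scaffold protein of these receptors (1.73-fold lower, 0.0457). The HOMER1 call over all genes held in 6 of 9 other settings and in 0 of 6 fits with an array left out. SLC7A11, the light chain of the cystine-glutamate exchanger, was detected on 1 vehicle array and 3 riluzole arrays, and its groups overlapped (adjusted p = 0.254). Its heavy chain SLC3A2 had a log2 fold change of 0.33 ± 0.12 (SE, adjusted p = 0.217). The glutamate transporter SLC1A3 (0.20, adjusted p = 0.473) did not pass either. The list of glutamine and glutamate metabolism did not pass (0.319), although GPT2 and ASNS belong to it. Of the ion channels targeted by riluzole, 4 of 22 were detected, too few for a test, and the sodium channel SCN9A was 1.46-fold higher (0.0475). This SCN9A call held in 4 of 9 other settings, with adjusted p up to 0.154, and in 0 of 6 fits with an array left out.

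Targets of the aryl hydrocarbon receptor, a ligand-activated transcription factor, did not pass as a list (adjusted p = 0.907, 7 detected). CYP1A1 was not detected on any array (raw signal 92.6 ± 20.1 and 98.2 ± 3.92). CYP1B1 had a log2 fold change of -0.0036 (95% CI of the fold 0.816 to 1.22, adjusted p = 0.996), and TIPARP one of -0.17 (0.549). Replication-dependent histone genes did not pass as a list (0.319, 15 of 29 members detected). Of them H2BC5 was 1.52-fold higher (0.0411), and its further probe gave a log2 fold change of 0.34 (limma adjusted p = 0.205 over probes). Immediate early and MAPK feedback genes did not pass either (0.824), of which EGR1 was 2.05-fold higher (0.0377). The lists of DNA repair (0.0957), apoptosis regulators (0.366), autophagy and lysosome (0.588), glycolysis (0.588), oxidative phosphorylation (0.190), interferon response (0.963), ribosomal proteins (0.344) and reference genes (0.907) did not pass. Among markers of cell identity, mesenchymal and invasion genes (0.963), epithelial genes (0.320), luminal and hormone receptor markers (0.588), fibroblast and stromal markers (0.907) and immune cell markers (0.588) did not pass, and endothelial markers, with 3 detected, were not tested. For 5 of the tested lists the measures differ in sign. Immediate early genes had a median of 0.02, a mean of -0.0011 and a downward camera test, mesenchymal genes a median of -0.0077, a mean of 0.0086 and an upward test, and interferon genes a median of 0.02, a mean of 0.0071 and a downward test. In the p53 and fibroblast lists the median, mean and camera test were upward and fry downward.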

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

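The probe-level fit of this part was not among the tests planned before the data were examined. Probes without a usable gene name stayed out of the comparison of genes and were fitted with all 20788 detected probes, of which 145 passed limma's adjusted threshold. Of 1113 detected probes without a name, 3 differed between riluzole and vehicle, 2 higher and 1 lower. Probe ILMN_1856315 was higher with a log2 fold change of 0.94 (adjusted p = 0.0315), ILMN_1816157 was higher at 1.04 (0.0393), and ILMN_1844593 was lower at -0.74 (0.0337), with all 3 named by probe because the table pairs them with no symbol. Of 92 spike-in probes of the ERCC set, 0 were detected on any array. Groups of 3 arrays are too small for a test of single outlying arrays.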

How the results depend on the processing

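Of the settings below, neqc with the negative control probes was chosen after seeing the data; it gave the same count of 176 genes and 9 lists. All 176 genes kept their direction in every setting that tested all of them, 135 of 135 did under the strict detection filter, and 171 of 171 or 167 of 168 did with 1 array left out. With an array left out the direction was close to fixed, as the groups of each of these genes did not overlap. The count was 563 with quantile normalization and no background correction, 94 with the authors' processed values, 70 without a detection filter, 360 with detection under 0.01 on all 6 arrays and 661 with an intensity trend and robust variance, and it ran from 21 to 41 with 1 array left out, where fewer arrays leave less power. Without the filter 30818 genes were tested in place of 14887, and with the strict filter 11870. For the other counts the cause was not tested. Median scaling gave 160, array weights 219 and the mean of probes 197.

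The replicate numbers did not pair the arrays: deviations of same-numbered arrays from their group means correlated at -0.146, -0.105 and 0.0011, and 0 of 6 arrays correlated best with their own number. With the replicate block 22 genes passed, 20 of them among the 176.

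Of the lists, 9 passed, and between 9 and 12 in the other settings except camera with an estimated correlation, which left 3. Mitosis, cholesterol biosynthesis and G1/S passed in all 12 alternatives and with each array left out, with highest adjusted p of 0.0124, 0.0190 and 0.0369. The fits with an array left out used camera at the preset correlation, at which lists passed in every split of the arrays. Passing them is therefore weak support. The estimated correlation was not combined with a left-out array or another normalization. The 9 lists under fry hold oxidative phosphorylation (adjusted p = 0.00859) in place of NF-kB (0.0816). The unfolded protein response passed in 4 of 12 alternatives and in 3 of 6 fits with an array left out. Glutamate receptors and transporters passed with the strict filter (0.0212), and heat shock (0.0368) and DNA repair (0.0467) without a filter.

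Reversals were of lists and genes near 0, and their cause was not tested. The mean log2 fold change of the p53 list was -0.00399 without background correction, -0.00310 with median scaling and -0.0155 with the strict filter. That of interferon genes was -0.0113 with median scaling, -0.0146 without the filter and -0.00112 with the mean of probes. That of mesenchymal genes was -0.0120 with median scaling, -0.00327 with the authors' values and -0.0221 without the filter. Aryl hydrocarbon receptor targets were at -0.000373 with median scaling, immediate early genes at 0.0499 without the filter and 0.0151 with the mean of probes, and reference genes at 0.00472 with array weights. With 1 array left out, the ranges that crossed 0 were -0.109 to 0.0937 for CYP1B1, -0.0800 to 0.0915 for CCND1, -0.0127 to 0.0738 for aryl hydrocarbon receptor targets, -0.0527 to 0.0141 for NRF2 targets, -0.0161 to 0.0254 for the p53 list, -0.0149 to 0.0200 for interferon genes, -0.0441 to 0.0548 for immediate early genes, -0.00400 to 0.0359 for mesenchymal genes, -0.0247 to 0.0907 for fibroblast markers and -0.0268 to 0.0310 for reference genes. For named genes, the other settings gave the same side of the threshold in 518 cases, a lost call in 75 and a new call in 2, and fits with an array left out lost 188 calls. Signal over background limits dim genes: ANGPTL4, P8, LOC100170939, IL16, RIMS2, SLC7A11 and SCN9A lie near the detection limit with at least 1 treatment.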

Other observations

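In this part the tests of normalization, of carried-over small RNA and of less small RNA were chosen only after the result was seen. Bootstrap intervals here resampled the genes of a set as if independent, so they do not measure the spread between arrays. The gene lists used here were written after the genes with the largest changes had been seen and before their own values as lists were. Members such as SCD, SREBF1 and PLIN2 also belong to the main list of fatty acid and lipid synthesis, so the lists are not fully separate from it. In all, 7 such lists were tested as 1 family with camera. Of other genes of G2 and mitosis, 42 were detected and 6 passed over all genes, all higher: KIF14 (log2 fold change 0.75), CDCA8 (0.77), HJURP (0.71), PSRC1 (1.01), CDCA2 (0.58) and KIF18A (0.74), proteins of the spindle, the centromere and chromosome segregation. Adjusted over the list alone, 18 rose. The 10 cytosolic aminoacyl-tRNA synthetases outside the ATF4 list had a median log2 fold change of 0.03 (adjusted p = 0.768). Within the ATF4 list WARS1 (0.54), CARS1 (0.51), YARS1 (0.47) and AARS1 (0.39), chosen after their values were seen, passed only when adjusted over the list alone, and EPRS1 (0.19) and NARS1 (0.13) passed by neither count. GARS (0.32), MARS (0.45) and SARS (0.36) keep array names that are synonyms of several genes, so they were not matched to the list. The 17 mitochondrial synthetases were lower as a list, 16 of them negative (adjusted p = 0.0439; adjusted p = 0.128 with an estimated correlation), and 0 passed singly in the limma fit, where 2430 of all genes had an unadjusted p under 0.05.

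Mitosis genes rose while DNA replication genes fell, in 31 of 33 and 35 of 40 members by sign. Another normalization did not account for it, since over 3 others the largest camera adjusted p of both lists was 2.51e-08 at the preset correlation. Nor did the signal level of the genes, since the central 95% of 10000 random lists matched on signal had medians up to 0.0595 for the mitosis list, against 0.54 observed, and down to -0.0617 for the replication list, against -0.20. A candidate explanation is a larger share of cells in G2/M and a smaller one in G1/S or S: the further G2/M genes rose (median 0.29, adjusted p = 6.22e-12; adjusted p = 0.0474 with an estimated correlation), and the further S-phase genes were lower (median -0.10, bootstrap 95% interval -0.29 to 0.04, adjusted p = 0.0379), a call lost with an estimated correlation (adjusted p = 0.128), with 16 of 25 members negative, 1 that fell over all genes, and 4 that fell and 2 that rose (ASF1B, 0.54, and MCM8, 0.44) adjusted over the list alone. The further lists hold genes of the same phases as the main lists, read on the same arrays, so they are not independent of them. A transcriptional effect on the genes of these phases could move both alike, so the further lists cannot tell the explanations apart. Transcriptional effects of riluzole at an unchanged cell cycle stay open, as no measure of DNA content was used here.

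Cholesterol synthesis genes fell in 24 of 25 members by sign. The other normalizations kept this, with a largest camera adjusted p of 5.95e-12 at the preset correlation. The central 95% of random lists matched on signal had medians down to -0.0825, against -0.37 observed. An excess of sterol that lowers SREBP activity and also activates LXR would raise LXR targets. The 13 detected genes of the LXR list had a median log2 fold change of -0.0555 (bootstrap 95% interval -0.19 to 0.08), which argues against that. Whether LXR responds in these cells was not tested, and an excess of sterol without LXR activation stays open. Without SREBF1 and SCD, which SREBP also regulates, the median of the other 11 was -0.0196 (-0.126 to 0.160). A fall of SREBP activity by another route may underlie the pattern, and neither that nor an effect of the cell cycle on these genes was tested.

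Probes of small noncoding RNAs stood out among the calls, in a preparation by spin column, a kind of kit that retains short RNA poorly. Whether these probes read the mature small RNAs was not tested, so the changes are those of probe signals. A single change in how much short RNA was carried over would move them one way, whereas 6 rose and 12 fell. The level of the mature host transcript does not account for them as a group: of 14 called small RNAs with a measured host, 2 had a host that moved alike and by a comparable amount, at least 0.5 times as much (SNORA16A and SNORA61, both in SNHG12), and 0 hosts passed the threshold, which leaves host transcription itself open. For the 12 that fell, a lower yield of small RNA in the riluzole preparations may contribute, since all 135 tested had a median log2 fold change of -0.184 and the 117 not past the threshold one of -0.170 (bootstrap 95% interval -0.231 to -0.0927). That account holds only if these probes read the short RNAs themselves. It leaves the rise of SNORD46, SNORA17B, SNORA84, SNORD1A, SNORD13 and SNORD11B open.

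For the rise of ANGPTL4, the hypothesis of a general activation of PPAR targets was tested on 12 other detected targets. Their median log2 fold change was 0.274 (bootstrap 95% interval 0.04 to 0.37) and they were higher as a list (adjusted p = 0.00528), which is consistent with it, but the call was lost with an estimated correlation (adjusted p = 0.101). Over all genes 0 of the 12 passed in the limma fit, and 4 rose when adjusted over the list alone: PDK4 (0.69), PLIN2 (0.42), ACADVL (0.35) and ETFDH (0.33). PLIN2 is also the member that rose in the fatty acid and lipid synthesis list. The ANGPTL4 rise itself rests on 1 of 2 probes. A hypothesis that snoRNA host genes, substrates of nonsense-mediated decay, rise together with ATF4 targets was not borne out (median -0.06, adjusted p = 0.302), nor was one that the mitochondrial synthetases rise with the ATF4 list, whose median had an upper 95% bootstrap bound of -0.0267.

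The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 of the 10 splits gave as many as 176, the real one, and the highest of the others gave 0. For lists, 1 of the 10 gave as many as 9, the real one, and the others gave between 1 and 7. At the preset correlation, lists thus passed in every split, also where 0 genes passed. A list call alone is therefore weak support for a treatment effect. Each other split keeps unequal numbers of riluzole arrays on its sides, so its calls may hold part of that effect.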
